A study of Homo sapiens with 9 samples.

How the data were processed

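RNA from 9 libraries labelled as the human colorectal adenocarcinoma line HCT-15 was analysed, 3 each of untreated control, CoCl2-tolerant and low-glucose-tolerant cells. Per the labels' protocols, cells grew in RPMI medium with 10% fetal bovine serum, and the tolerant lines were derived by growth in rising concentrations of the agent. The labels' protocols also state that RNA was extracted with TRIzol and that mRNA was isolated, sheared, reverse-transcribed, amplified and sequenced on an Illumina NovaSeq. Per the submitters' processing notes, featureCounts, DESeq2 and genome build GRCh38 were used, with no versions. The aligner, annotation release and strand setting are not given in the sources used here. The deposited files hold a raw read count per gene and library, checked as whole numbers whose totals differ between libraries. They list the same 36018 genes in all 9 libraries. Of the gene identifiers, 35938 carried a symbol and 76 more were named from GENCODE release 29, which also gave positions, gene types, transcript lengths and exon overlaps for 34888 genes.

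Depth ranged from 25178615 to 32674687 counts per library. Differential expression used edgeR 4.0.16 in R 4.3.3, on genes passing filterByExpr by group (17902 genes). Scaling used trimmed means of M values (TMM factors 0.922 to 1.04). A quasi-likelihood F test was fitted to all 9 libraries with one mean per group and no covariate (common biological coefficient of variation 12.6%, prior degrees of freedom 8.29). P-values were adjusted by the Benjamini-Hochberg method within each comparison and called under 0.05, with a second count for changes of at least 2-fold. The comparisons were CoCl2-tolerant against control, low-glucose-tolerant against control, and the tolerant lines against each other. Genes past the threshold in both comparisons against control were also counted. Gene sets were 31 lists of genes fixed before the data were examined, tested where at least 5 members passed the filter. The set test was camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists. Members passing the gene test were counted after adjustment over all genes and over the list alone. CPM use each library's total times its TMM factor as the denominator. Ratios of genes with few counts carry 95% intervals for counting error. A group with no counts is set to a floor of 3 counts over the group. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

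Genes are named by a rule. It takes the 5 largest rises and 5 largest falls per comparison against control (3 each way in the direct comparison) among genes with a symbol, an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between libraries. It adds 22 genes fixed by name whatever their values, and up to 4 members per list and comparison with the largest changes among those that passed with at least 1 CPM in the higher group. Pseudogenes are counted but not named, and some genes that the rule names are not reported here.

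The procedure was tested on simulated counts of 17209 genes. It recovered 54.3, 94.0 and 100% of genes changed 1.5-fold, 2-fold and 4-fold in the CoCl2-tolerant comparison, with 5.29% false calls. The low-glucose-tolerant comparison recovered 46.3, 89.6 and 100% with 3.68% false calls, and the direct comparison 55.3, 93.3 and 100% with 3.90%. A list shifted in the simulated CoCl2-tolerant group alone was called by limma's camera in the 2 comparisons with that group (adjusted p = 1.86e-47 and 1.02e-31) and not in the third (adjusted p = 0.998). The simulated genes varied independently of each other, so calls on lists whose members vary together were not tested. Apart from that list, the changed genes were well-counted ones, and far fewer genes were changed than in the data. Replicate pairs were checked for duplicates and differed by more than counting error in every group, with chi-squared per degree of freedom of 2.31 to 6.87 in control, 8.36 to 32.8 in CoCl2-tolerant and 27.2 to 74.1 in low-glucose-tolerant pairs. Residuals of libraries with the same replicate number in different groups correlated at -0.608 to 0.338, and with different numbers at -0.701 to 0.617, so the numbers were not taken to pair the libraries.

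Alternatives were the DESeq2 1.42.0 Wald test, DESeq2 size factors, library totals, no filter, a stricter filter (at least 5 CPM in 3 libraries), a fit of only the 2 groups compared, a block for the replicate number, and each library left out in turn. For lists they were camera with an estimated correlation and the rotation test fry. Alternatives added after the data were seen left out the mitochondrially encoded genes or the genes of chromosomes 5, 7, 15 and 16, or removed a per-library trend on transcript length and GC content fitted by splines. Chromosome summaries used 10413 protein-coding autosomal genes with a mean log2 CPM over 2. The brefeldin A-tolerant line and sequence reads were not used here.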

Results

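Gene expression was measured by RNA sequencing in cells labelled as HCT-15, an established human colorectal adenocarcinoma cell line, and in lines derived from them. The derived lines were cultured in rising amounts of a stressor until the cells tolerated it. The label was not checked against a reference library of HCT-15, and 26 of 29 listed intestinal markers were under 1 CPM in every group. One derived line tolerated cobalt chloride (CoCl2), a salt that mimics hypoxia by blocking the enzymes that mark hypoxia-inducible factors (HIF) for breakdown. Another tolerated low glucose, which starves cells of the main substrate of glycolysis and of sugars for protein glycosylation in the endoplasmic reticulum (ER). The untreated control, the CoCl2-tolerant line and the low-glucose-tolerant line had 3 libraries each, 9 in all. The series concerns inositol hexaphosphate, ER stress, senescence and chemotherapy. The comparisons below ask how each tolerant line differed from the untreated line, which changes both lines had in common, and how the lines differed from each other. The brefeldin A-tolerant line named in the study's description was not analysed here.

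Gene counts summed to 30075024, 32674687 and 31097069 in the control libraries, to 25178615, 27829153 and 27136192 in the CoCl2-tolerant libraries, and to 30115866, 30069786 and 29971930 in the low-glucose-tolerant libraries. At these depths, before TMM scaling, 3 counts in a library corresponded to 0.0918 to 0.119 CPM (counts scaled to library size). Mitochondrially encoded genes took 8.08 to 9.80% of the counts in control libraries, 4.64 to 6.67% in CoCl2-tolerant and 4.74 to 5.196% in low-glucose-tolerant libraries. Cytosolic ribosomal protein genes took 3.52 to 3.67%, 4.29 to 5.35% and 7.25 to 10.8%, respectively. Levels below are means ± SD in CPM over the 3 libraries of a group (n = 3), and fold changes are on the log2 scale ± SE. The labels do not say that the 3 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. Each tolerance is represented by a single derived line. A difference from control can therefore not be told apart from other changes during the culture of that line. The first principal component of log2 CPM held 69.2% of the variance and set the low-glucose-tolerant libraries apart from the other 6, and the second held 17.1% and set the CoCl2-tolerant libraries apart from the control. Low-glucose-tolerant replicate 2 lay apart from its group on the second component (-19.9, against -0.73 and 1.59), and its pairs differed more, with a chi-squared per degree of freedom of 56.2 and 74.1 against 27.2 for replicates 1 and 3. Without it 7965 genes changed in the CoCl2-tolerant line, against 6459.

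**Figure D1:**
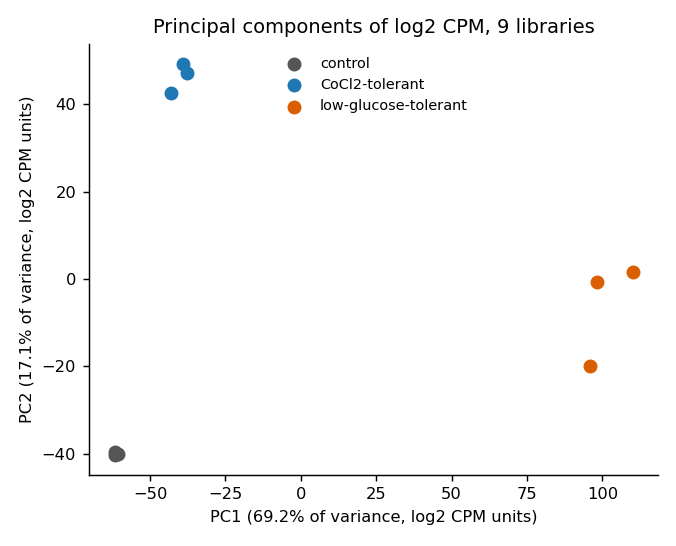
Principal components of log2 CPM, with each of the 9 libraries as a point coloured by group (axes in log2 CPM units). The first component (69.2% of the variance) separates the low-glucose-tolerant libraries from the others and the second (17.1%) separates the CoCl2-tolerant libraries from the control, with the 3 control libraries almost on top of each other.

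The first comparison asked what distinguished CoCl2-tolerant from untreated cells. The largest rise was in HMOX1, the heme oxygenase that degrades heme under oxidative stress, from 53.6 ± 1.19 CPM in control to 1811 ± 180.0 CPM (log2 fold change 5.08 ± 0.17). ADM, the hypoxia-induced peptide adrenomedullin, rose from 6.80 ± 0.579 to 94.4 ± 4.31 CPM, and the aldo-keto reductase AKR1B10 from 0.975 ± 0.286 to 11.3 ± 1.43 CPM. C2orf72 and LURAP1L completed the 5 largest rises, at 10.2 ± 0.971 and 10.6 ± 0.198 CPM against 1.11 ± 0.0828 and 1.41 ± 0.329 in control. The largest falls were in RASL12, a small GTPase of the RAS-like family, LARGE2, a glycosyltransferase that extends the sugar chains of dystroglycan, FLJ16779, SEMA6B, a semaphorin guidance factor, and ACTC1, the cardiac actin. RASL12 had 9 counts over the CoCl2-tolerant libraries against 783 in control, a ratio of 73.9 (95% interval 38.7 to 162, which like the later intervals on count ratios covers counting error only). LARGE2 fell from 10.4 ± 0.245 to 0.183 ± 0.0569 CPM, FLJ16779 from 27.8 ± 0.234 to 1.34 ± 0.247, SEMA6B from 26.9 ± 1.37 to 1.58 ± 0.243 and ACTC1 from 7.22 ± 1.002 to 0.455 ± 0.217 CPM. Each of these genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 4.92e-10 (HMOX1) to 7.98e-08 (ACTC1), and all 3 libraries of the higher group lay above all 3 of the lower. HMOX1 lies on chromosome 22, 35380361 to 35394214 (GRCh38, gene ENSG00000100292) and ADM on chromosome 11, 10304680 to 10307397. LARGE2 lies on chromosome 11, 45921621 to 45929096 and SEMA6B on chromosome 19, 4542593 to 4559808. Values are for whole genes, summed over their exons.

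By edgeR's test, 6459 of 17902 genes changed in the CoCl2-tolerant line (36.1%), 3204 of them higher and 3255 lower. Of these, 1983 changed at least 2-fold (822 higher and 1161 lower) and 359 at least 4-fold. With a stricter filter (at least 5 CPM in 3 libraries), 779 of 11673 genes changed at least 2-fold (324 higher and 455 lower). In 57.2% of genes the libraries of the groups did not overlap, against 10% by chance for 3 against 3. Of the 31 gene lists fixed before the data were examined, 30 had enough tested members for a set test. In the CoCl2-tolerant line, limma's camera with a preset correlation called 20, and 9 of these held with an estimated correlation. Where no second count is given for a list here and in the later comparisons, the counts adjusted over the list alone were the same.

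Hypoxia and glucose metabolism genes were higher in the CoCl2-tolerant line. Among 44 tested HIF targets, 39 rose and 5 did not pass (camera adjusted p = 6.80e-47, median log2 fold change 1.15). The tumour-associated carbonic anhydrase CA9 rose from 12 counts over the control libraries to 202, though 38.5% of its exon bases are shared with a gene on the opposite strand. The glucose transporter SLC2A1 rose from 444 ± 10.6 to 812 ± 80.2 CPM. VEGFA, the angiogenic growth factor, was at 194 ± 0.707 and 211 ± 8.79 CPM (edgeR adjusted p = 0.327). Of 24 glycolysis genes, 19 rose (20 adjusted over the list alone), among them the enolase ENO2, from 119 ± 1.64 to 478 ± 77.2 CPM, and PFKFB4, which sets the level of an activator of phosphofructokinase, from 16.1 ± 0.356 to 50.6 ± 4.28 CPM. That list had a camera adjusted p = 1.49e-15, and adjusted p = 0.0504 with an estimated correlation. The list of glucose-sensing and gluconeogenic genes passed (camera adjusted p = 1.62e-04) with 4 of 10 genes higher and 1 lower. TXNIP and ARRDC4, arrestin-family genes switched on by the glucose sensor MondoA, rose from 63.8 ± 1.57 to 299 ± 11.2 CPM and from 5.54 ± 0.394 to 27.5 ± 2.89 CPM.

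Targets of the integrated stress response, which acts through the transcription factor ATF4, rose in 30 of 35 cases and fell in 1 (camera adjusted p = 4.56e-36). ATF4 itself rose from 309 ± 9.03 to 597 ± 78.8 CPM. DDIT3, which encodes the pro-apoptotic factor CHOP, rose from 8.12 ± 0.425 to 39.4 ± 2.69 CPM, though 39.6% of its exon bases are shared with other genes on either strand and the strand setting is not known, and TRIB3, a pseudokinase induced by CHOP, from 43.9 ± 2.47 to 160.1 ± 16.9 CPM. The glutathione-degrading enzyme CHAC1 rose from 5.81 ± 0.562 to 42.9 ± 6.86 CPM and the cystine transporter SLC7A11 from 18.1 ± 0.510 to 105 ± 16.5 CPM. ASNS, asparagine synthetase, was read as 1.31 ± 0.0652 and 2.18 ± 0.295 CPM, with 44.6% of its exon bases shared with another gene, so its level is uncertain. The list of ER chaperones, folding enzymes and ER-associated degradation did not pass, with 10 of 36 genes higher and 3 lower (camera adjusted p = 0.115). HERPUD1, a component of ER-associated degradation, rose from 37.4 ± 0.941 to 71.2 ± 2.93 CPM. The ER chaperone HSPA5 (BiP) was at 532 ± 9.26 and 685 ± 37.3 CPM (edgeR adjusted p = 0.0160) and the unfolded protein response factor XBP1 at 36.9 ± 0.445 and 46.9 ± 0.904 CPM (edgeR adjusted p = 0.0124). Both of these calls ended when any single control library or CoCl2-tolerant replicate 3 was left out, at edgeR adjusted p of 0.0573, 0.0656, 0.0610 and 0.0747 for HSPA5 and 0.0533, 0.0535, 0.0620 and 0.0510 for XBP1. The log2 fold changes there were 0.37, 0.35, 0.36 and 0.32 for HSPA5 (0.36 with all libraries) and 0.35, 0.35, 0.34 and 0.34 for XBP1 (0.35), with fewer libraries in the test. Over all alternatives the edgeR or DESeq2 adjusted p ranged over 0.00126 to 0.0747 for HSPA5 and 0.00168 to 0.0620 for XBP1. The chaperone list passed without CoCl2-tolerant replicate 1 (camera adjusted p = 0.0483, range over the alternatives 0.00291 to 0.380).

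The p53 and antioxidant programmes were higher. Among genes activated by p53, the tumour suppressor that halts damaged cells, 23 of 25 rose (adjusted over the list alone, 23 rose and 1 fell; camera adjusted p = 1.67e-16). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 184 ± 2.81 to 491 ± 21.4 CPM, GADD45A, a DNA damage response gene, from 40.9 ± 1.80 to 191 ± 13.4, and BBC3, the pro-apoptotic protein PUMA, from 10.5 ± 0.0410 to 31.9 ± 3.61 CPM. Targets of the oxidative stress factor NRF2 rose in 25 of 29 cases (camera adjusted p = 2.62e-25), HMOX1 and AKR1B10 among them. The senescence marker list passed with 8 of 19 genes higher and 1 lower (camera adjusted p = 0.00120, and adjusted p = 0.121 with an estimated correlation). LMNB1, the nuclear lamina protein lost in many senescent cells, fell from 147 ± 2.29 to 95.8 ± 2.29 CPM, and CDKN2A, which encodes p16, was under the filter with 12 counts over all 9 libraries. GDF15, a stress-induced cytokine, rose from 107 ± 6.25 to 354 ± 10.9 CPM. Factors of the senescence-associated secretory phenotype rose in 20 of 50 cases and fell in 6 (7 adjusted over the list alone), with SERPINE2 going from 22.1 ± 0.610 to 143 ± 5.47 CPM. That list passed as higher (camera adjusted p = 0.0108, and adjusted p = 0.161 with an estimated correlation), with a median of 0.07 but a mean of -0.05. The call was also lost with the length and GC trend removed (camera adjusted p = 0.1002, with 0.161 the highest over the alternatives). BCL2 family and death receptor genes rose in 14 of 31 cases and fell in 3 (15 and 5 adjusted over the list alone), with a camera adjusted p = 0.0149 and adjusted p = 0.0690 with an estimated correlation.

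Autophagy and lysosome genes rose in 21 of 38 cases and fell in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 3.52e-07), and the cargo receptor SQSTM1 rose from 572 ± 7.25 to 1829.9 ± 38.3 CPM. Lipid synthesis genes fell. Of 25 sterol synthesis genes, 14 fell (15 adjusted over the list alone; camera adjusted p = 3.77e-05). Of 13 fatty acid synthesis genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 2.25e-05, and adjusted p = 0.0706 with an estimated correlation). Fatty acid synthase, FASN, fell from 833 ± 20.03 to 306 ± 51.9 CPM. Epithelial junction and keratin genes fell in 12 of 21 cases and rose in 2 (13 and 2 adjusted over the list alone; camera adjusted p = 3.56e-08). CDH1, the adhesion molecule E-cadherin, fell from 17.8 ± 0.466 to 1.41 ± 0.133 CPM and the epithelial transcription factor ELF3 from 56.2 ± 1.11 to 12.995 ± 0.199 CPM. The keratins did not fall together. KRT19 was at 539 to 562 CPM in the control and 819 to 1013 CPM in the CoCl2-tolerant libraries. KRT18 was at 103 to 110 and 90.9 to 109 CPM, and KRT8 at means of 658 and 494 CPM.

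Most proliferation genes did not pass. G2/M genes fell in 10 of 38 cases and 28 did not pass (camera adjusted p = 0.0108, and adjusted p = 0.421 with an estimated correlation) and MKI67, a marker of dividing cells, fell from 433 ± 23.5 to 221 ± 24.6 CPM. DNA replication genes fell in 15 of 44 cases and rose in 1, and 28 did not pass (camera adjusted p = 0.00943, and adjusted p = 0.428 with an estimated correlation). Mitochondrially encoded genes fell in 12 of 13 cases (camera adjusted p = 4.05e-06, and adjusted p = 0.266 with an estimated correlation), beside the lower mitochondrial share of counts given above. Nuclear-encoded respiratory subunits rose in 11 of 53 cases (6 adjusted over the list alone; camera adjusted p = 0.0189, and adjusted p = 0.690 with an estimated correlation). That call was lost without CoCl2-tolerant replicate 1 (camera adjusted p = 0.135) and with the length and GC trend removed (0.0603), with 0.690 the highest over the alternatives. Cytosolic ribosomal protein genes rose in 36 of 61 cases (40 adjusted over the list alone; camera adjusted p = 2.22e-06, and adjusted p = 0.479 with an estimated correlation). Replication-dependent histone genes rose in 8 of 14 cases (camera adjusted p = 6.55e-05). Their transcripts lack a poly(A) tail and so may vary with the RNA selection, which was not tested. Fibroblast markers fell in 3 of 7 cases (camera adjusted p = 5.72e-05, and adjusted p = 0.142 with an estimated correlation), led by the collagen gene COL1A1, from 1857 ± 27.4 to 250.3 ± 17.2 CPM.

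The remaining lists did not pass camera in the CoCl2-tolerant line. Metal response genes rose in 5 of 17 cases and fell in 4 (6 and 4 adjusted over the list alone; camera adjusted p = 0.397). The metallothionein MT2A rose from 713 ± 75.6 to 1289 ± 46.3 CPM and the ferritin light chain FTL from 1550.5 ± 52.7 to 4214 ± 323 CPM. Inositol phosphate genes rose in 6 of 42 cases and fell in 14 (camera adjusted p = 0.115). ITPKA, which phosphorylates inositol trisphosphate, rose from 4.76 ± 0.288 to 15.9 ± 2.47 CPM, and ITPK1, a kinase on the route to inositol hexaphosphate, fell from 78.4 ± 1.79 to 47.9 ± 6.08 CPM. IPPK, which makes inositol hexaphosphate, was at 3.56 ± 0.490 and 3.57 ± 0.395 CPM (edgeR adjusted p = 0.995), with 72.0% of its exon bases shared with a gene on the opposite strand, and MINPP1, a phosphatase that degrades it, at 34.2 ± 1.35 and 33.7 ± 0.600 CPM (edgeR adjusted p = 0.899). Drug efflux and metabolism genes rose in 4 of 28 cases and fell in 8 (camera adjusted p = 0.195), and the efflux pump ABCB1 was at 14.03 ± 0.829 and 11.3 ± 1.27 CPM (edgeR adjusted p = 0.0870, or 0.0481 without low-glucose-tolerant replicate 2, over a range of 0.0323 to 0.391). Rises and falls were 11 and 10 (11 and 11 adjusted over the list alone) of 35 mesenchymal genes (camera adjusted p = 0.477), with a median of 0.06 but a mean of -0.08 and a test direction of lower. They were 3 and 9 of 17 Wnt and crypt stem cell genes (camera adjusted p = 0.130), 12 and 8 of 44 interferon-stimulated genes (0.501) and 9 and 4 of 23 NF-kappaB targets (0.341). Leukocyte markers counted 1 and 1 of 9 (camera adjusted p = 0.768), with median and mean of -0.08 and -0.03 but a test direction of higher. Of 4 tested endothelial markers, too few for camera, 3 fell. Intestinal differentiation markers counted 1 rise and 2 falls (1 and 3 adjusted over the list alone) among 6 tested of 34 fixed (camera adjusted p = 0.768), and 26 of the 29 listed were under 1 CPM in every group.

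**Figure D2:**
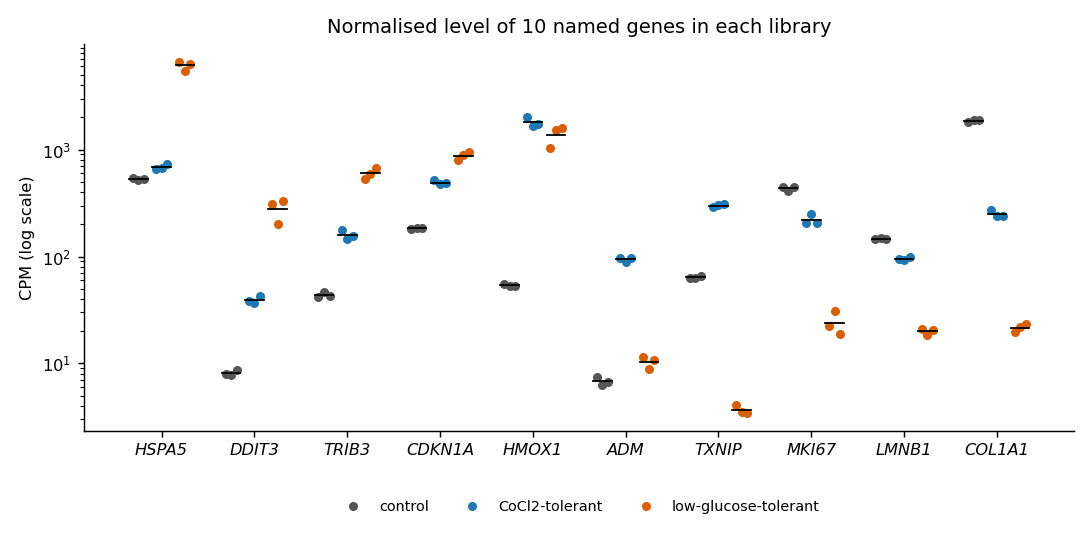
CPM on a log axis of 10 named genes in each of the 9 libraries, coloured by group, with a line at the group mean. HSPA5 lies near 532 CPM in control and 685 CPM in the CoCl2-tolerant line but at 6120.4 CPM in the low-glucose-tolerant line, while TXNIP is highest in the CoCl2-tolerant and lowest in the low-glucose-tolerant line.

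The second comparison asked what distinguished low-glucose-tolerant from untreated cells. ER stress genes rose and cell division genes fell. HSPA5 rose from 532 ± 9.26 to 6120.4 ± 618 CPM (log2 fold change 3.52 ± 0.12, edgeR adjusted p = 1.62e-11), DDIT3 from 8.12 ± 0.425 to 279 ± 69.0 CPM and XBP1 from 36.9 ± 0.445 to 243 ± 15.7 CPM. MKI67 fell from 433 ± 23.5 to 24.1 ± 6.17 CPM and LMNB1 from 147 ± 2.29 to 19.99 ± 1.498 CPM. The largest rises were in KLHDC7B, HSPA6, an inducible HSP70 chaperone, THBD, the anticoagulant receptor thrombomodulin, LAMP3, a lysosomal membrane protein induced by ER stress, and the antisense transcript MSC-AS1. HSPA6 rose from 0.247 ± 0.132 to 38.0 ± 10.2 CPM, THBD from 0.478 ± 0.0878 to 38.1 ± 4.96 and LAMP3 from 0.506 ± 0.209 to 37.2 ± 8.27 CPM. KLHDC7B had 669 counts over the low-glucose-tolerant libraries against 3 in control, a ratio of 249 (95% counting interval 84.8 to 1210), and MSC-AS1 589 against 9 (73.1, 38.2 to 161). Among the largest falls were IGFL2-AS1, with 2 counts against 760 in control (ratio 340, 93.9 to 2816), FGFR2, a fibroblast growth factor receptor, COL1A1 and PSG3, a pregnancy-specific glycoprotein. FGFR2 fell from 98.1 ± 2.06 to 1.04 ± 0.468 CPM, COL1A1 from 1857 ± 27.4 to 21.5 ± 1.86 and PSG3 from 110.1 ± 2.68 to 1.42 ± 0.382 CPM. These 9 genes passed edgeR's test with adjusted p of 1.70e-09 or less. Without control replicate 3 the log2 fold change of KLHDC7B went from 7.78 to 8.62. HSPA5 lies on chromosome 9, 125234853 to 125241330 (GRCh38, gene ENSG00000044574), HSPA6 on chromosome 1, 161524540 to 161526910, FGFR2 on chromosome 10, 121478334 to 121598458 and COL1A1 on chromosome 17, 50183289 to 50201632.

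In the low-glucose-tolerant line 12394 of 17902 genes changed by edgeR's test (69.2%), 6194 of them higher and 6200 lower. Of these, 6572 changed at least 2-fold (2815 higher and 3757 lower) and 2192 at least 4-fold. The stricter filter gave 3404 of 11673 genes at least 2-fold (1548 higher and 1856 lower). Libraries did not overlap in 73.3% of genes, against 10% by chance. Camera called 14 of the 30 tested lists, 5 of which held with an estimated correlation. Scaling by library totals in place of trimmed means moved the median of all genes by -0.10 on the log2 scale in this line, and 44.9% of the calls were then higher, against 49.98%, so changes are relative to that choice.

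The ER stress and integrated stress response lists rose almost throughout. Of 36 ER chaperone and folding genes, 33 rose and 2 fell (camera adjusted p = 2.09e-15, median log2 fold change 1.09). DNAJB9, a co-chaperone of BiP, rose from 6.05 ± 0.410 to 93.0 ± 12.1 CPM and HERPUD1 from 37.4 ± 0.941 to 448 ± 45.1 CPM. Integrated stress response targets rose in 33 of 35 cases and fell in 1 (camera adjusted p = 1.12e-28, median 2.05). ATF4 rose from 309 ± 9.03 to 977 ± 166 CPM, TRIB3 from 43.9 ± 2.47 to 599 ± 72.0, the stress-induced regulator NUPR1 from 9.15 ± 1.20 to 182 ± 40.2, and ASNS, uncertain for its shared bases, from 1.31 ± 0.0652 to 5.44 ± 0.824 CPM. Genes activated by p53 rose in 24 of 25 cases (camera adjusted p = 2.42e-12), with CDKN1A going from 184 ± 2.81 to 877 ± 77.9 CPM. NRF2 targets rose in 20 of 29 cases and fell in 2 (camera adjusted p = 1.11e-08). HMOX1 rose from 53.6 ± 1.19 to 1383 ± 309 CPM and OSGIN1, an oxidative stress-induced growth inhibitor, from 5.91 ± 0.800 to 215 ± 40.0 CPM.

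Cell division genes fell. All but 1 of the 38 G2/M genes were lower (camera adjusted p = 8.29e-40, median -2.38). The kinesins CENPE and KIF20A, which move chromosomes and complete cytokinesis, fell from 31.7 ± 1.68 to 1.17 ± 0.458 CPM and from 89.5 ± 3.76 to 3.51 ± 0.467 CPM. DNA replication genes fell in 36 of 44 cases and rose in 3 (camera adjusted p = 6.53e-13, and adjusted p = 0.0811 with an estimated correlation). The replication licensing factor CDT1 was among those that rose, from 33.2 ± 1.26 to 79.1 ± 10.4 CPM. The senescence marker list did not pass, with 10 genes higher and 8 lower of 19 (camera adjusted p = 0.851), a median of 0.32 but a mean of -0.05 and a test direction of lower. Camera tests for a shift in a common direction, so rises and falls within a list offset each other. Its result on this list therefore cannot decide for or against senescence, here or in the other comparisons. Secretory phenotype factors rose in 27 of 50 cases and fell in 13 (camera adjusted p = 0.0464, and adjusted p = 0.324 with an estimated correlation). That call was lost without control replicate 2 or 3 (camera adjusted p = 0.0680 and 0.0524) and with the length and GC trend removed (0.111), where 0.324 was the highest over the alternatives. The growth factors EREG and AREG, ligands of the epidermal growth factor receptor, rose from 8.61 ± 0.649 to 189 ± 40.7 CPM and from 3.21 ± 0.0599 to 55.1 ± 8.58 CPM, GDF15 rose from 107 ± 6.25 to 898 ± 107 CPM, and IGFBP3, a carrier of insulin-like growth factors, fell from 515 ± 13.7 to 36.4 ± 0.216 CPM.

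HIF target and glycolysis lists did not pass camera in this line with the settings chosen beforehand. Of 44 HIF targets, 12 rose and 24 fell (12 and 25 adjusted over the list alone; camera adjusted p = 0.138). CA9 had 0 counts over the low-glucose-tolerant libraries against 12 in control. With a floor of 3 counts over the group CA9 was 3.58-fold lower, and the lower limit of the counting interval for that fall was 2.49-fold. The list median of -0.40 was the same with CA9 set at that floor. VEGFA fell from 194 ± 0.707 to 121 ± 5.33 CPM and SLC2A1 from 444 ± 10.6 to 328 ± 32.2 CPM, while the neuronal-type glucose transporter SLC2A3 rose from 16.2 ± 1.22 to 59.2 ± 4.07 and ANGPTL4, an inhibitor of lipoprotein lipase, from 19.1 ± 0.0711 to 168 ± 27.8 CPM. Of 24 glycolysis genes, 8 rose and 14 fell (camera adjusted p = 0.194, or 0.0382 as lower with the length and GC trend removed, over a range of 0.00551 to 0.726), with the lactate dehydrogenase LDHA going from 1624 ± 24.6 to 536 ± 55.9 CPM. Glucose-sensing and gluconeogenic genes counted 3 rises and 5 falls of 10 (camera adjusted p = 0.143). TXNIP fell from 63.8 ± 1.57 to 3.68 ± 0.347 CPM and ARRDC4 from 5.54 ± 0.394 to 0.521 ± 0.0540 CPM. Sterol synthesis genes fell in 17 of 25 cases and rose in 4 (camera adjusted p = 5.98e-05, and adjusted p = 0.0811 with an estimated correlation). Fatty acid synthesis genes fell in 12 of 13 cases (camera adjusted p = 9.07e-05, and adjusted p = 0.104 with an estimated correlation), with the desaturase SCD going from 700.4 ± 14.8 to 128 ± 34.2 CPM.

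Cytosolic ribosomal protein genes rose in 59 of 61 cases (camera adjusted p = 9.13e-15, median 1.44, and adjusted p = 0.380 with an estimated correlation), beside their higher share of counts given above. That share was 7.25% in replicate 2, the library that lay apart, and 9.38 and 10.8% in the others. RPL13 rose from 620.0 ± 19.4 to 3326 ± 821 CPM. Metal response genes rose in 10 of 17 cases and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00774, and adjusted p = 0.0811 with an estimated correlation). MT2A rose from 713 ± 75.6 to 1853 ± 477 CPM and the metallothionein MT1M from 9.10 ± 0.760 to 64.3 ± 19.3 CPM. Autophagy and lysosome genes rose in 25 of 38 cases and fell in 3 (camera adjusted p = 0.00322, and adjusted p = 0.222 with an estimated correlation). MAP1LC3B, which coats autophagosomes, rose from 54.5 ± 0.751 to 291 ± 31.9 CPM. RPL13, MT2A, MT1M and MAP1LC3B lie on chromosome 16, as do HERPUD1, NUPR1, OSGIN1 and CDT1 above. Expressed genes of that chromosome had a median log2 fold change of 0.55 in this line, as set out below. The lists were not tested again without it. Mesenchymal genes fell in 19 of 35 cases and rose in 12 (camera adjusted p = 1.21e-04, and adjusted p = 0.239 with an estimated correlation). Fibroblast markers fell in 2 of 7 cases and rose in 1 (camera adjusted p = 0.0127, and adjusted p = 0.370 with an estimated correlation), with a median of 0.19 but a mean of -0.54 and a test direction of lower. The mesenchymal and fibroblast calls were lost with the length and GC trend removed (camera adjusted p = 0.0750 and 0.349, with 0.239 and 0.370 the highest over the alternatives).

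The other lists did not pass camera in the low-glucose-tolerant line, apart from the alternatives named. Epithelial genes rose in 13 of 21 cases and fell in 5 (camera adjusted p = 0.258), with keratin 18, KRT18, going from 107 ± 3.57 to 572 ± 110.3 CPM. Inositol phosphate genes rose in 13 of 42 cases and fell in 16 (camera adjusted p = 0.809). ITPKA rose from 4.76 ± 0.288 to 76.6 ± 12.4 CPM, its relative ITPKC from 6.79 ± 0.639 to 35.8 ± 5.33, and IPPK, with its shared bases, from 3.56 ± 0.490 to 5.74 ± 1.10 CPM. MINPP1 fell from 34.2 ± 1.35 to 24.9 ± 2.51 CPM, and ITPK1 was at 66.2 ± 6.33 CPM (edgeR adjusted p = 0.0731, or 0.0470 without low-glucose-tolerant replicate 2, over a range of 1.13e-04 to 0.252). Drug efflux and metabolism genes counted 9 rises and 10 falls of 28 (camera adjusted p = 0.698), with a median of -0.13 but a mean of 0.03. ABCB1 fell to 9.47 ± 1.24 CPM (edgeR adjusted p = 0.00178), a call lost with the length and GC trend removed (adjusted p = 0.111, the highest over the alternatives). Mitochondrially encoded genes fell in 9 of 13 cases and rose in 1 (camera adjusted p = 0.127). Nuclear-encoded respiratory subunits rose in 27 of 53 cases and fell in 4 (25 and 4 adjusted over the list alone; camera adjusted p = 0.111, or 0.00638 without low-glucose-tolerant replicate 2, where 0.815 was the highest over the alternatives). BCL2 family genes counted 16 rises and 6 falls of 31 (camera adjusted p = 0.111, or 0.0459 with the length and GC trend removed, over a range of 3.27e-05 to 0.222), interferon-stimulated genes 20 and 13 of 44 (0.522), and histone genes 4 and 2 of 14 (0.563). Wnt and stem cell genes counted 5 and 8 of 17 (5 and 9 adjusted over the list alone; camera adjusted p = 0.698), with a median of -0.31 but a mean of 0.12. NF-kappaB targets counted 6 and 8 of 23 (camera adjusted p = 0.851), with a median of -0.06 but a mean of 0.04. Leukocyte markers counted 2 and 1 of 9 (camera adjusted p = 0.851), with a median of -0.17 and a test direction of higher. Intestinal markers rose in 3 of 6 tested cases (camera adjusted p = 0.304), and 2 of 4 endothelial markers fell.

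**Figure D3:**
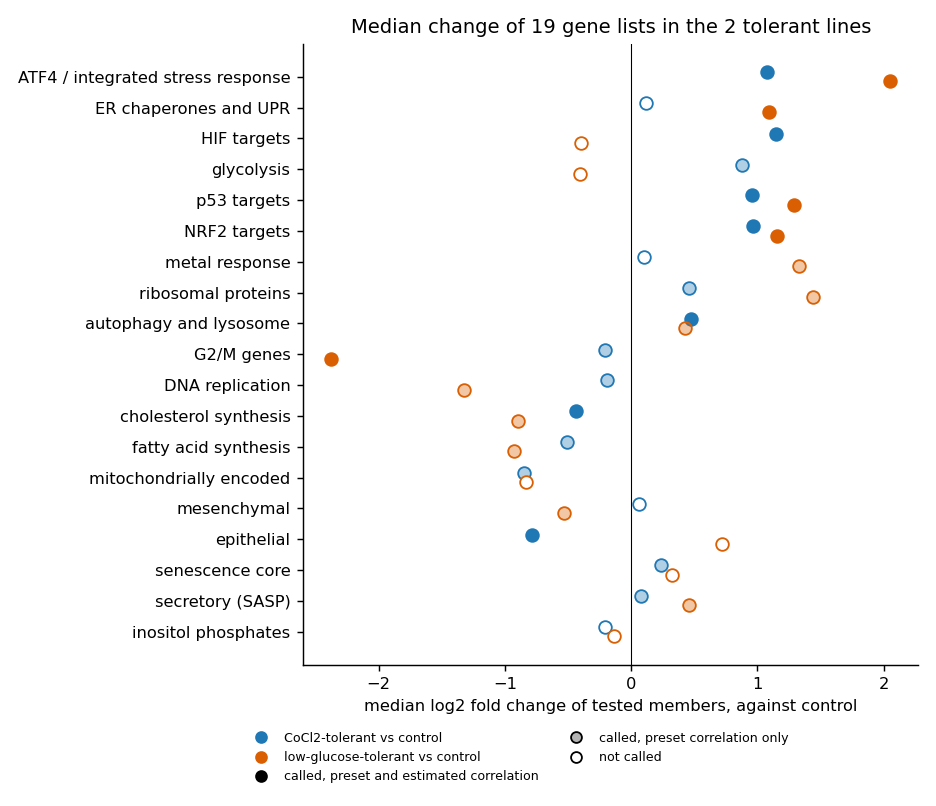
Median log2 fold change against control of the tested members of 19 gene lists, in the CoCl2-tolerant (blue) and low-glucose-tolerant (orange) lines. Filled points passed limma's camera with the preset and the estimated correlation, pale points with the preset correlation only, and open points did not pass. HIF targets have a median of 1.15 in the CoCl2-tolerant and -0.40 in the low-glucose-tolerant line, and G2/M genes of -0.20 and -2.38.

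The next comparison asked which changes both tolerant lines had in common. HMOX1, DDIT3, TRIB3, CDKN1A and GDF15 rose in both lines, and MKI67, LMNB1 and COL1A1 fell in both, with the values given above. TXNIP, ARRDC4 and SLC2A1 went in opposite directions. In all, 2018 genes rose in both and 2061 fell in both, 4079 with the same direction, against 1109 and 1127 for independent lists of these sizes. A further 902 passed in opposite directions (446 higher in the CoCl2-tolerant line only and 456 higher in the low-glucose-tolerant line only), against 2236 for independent lists. Without control replicate 1, 2 or 3 the opposite count was 565, 568 and 561. Both comparisons use the same 3 control libraries, so unchanged groups set against shared controls were simulated 20 times. The highest simulated count of genes passing in the same direction in both was 0, against 4079. Across genes, which are not independent replicates, the fold changes correlated at r = 0.417, where the simulation gave 0.483, and 66.3% had the same sign, where it gave 66.5%. Those simulated values arise from the shared controls whatever the size of the noise. They are therefore no measure of how far the changes in these data agree. The covariance of the fold changes, which depends on their size, was 0.412 against a simulated 0.0330, a difference of 0.379. The 3 controls cannot be split into groups of at least 2, so the overlap was not measured against separate controls.

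The last comparison set the tolerant lines directly against each other. PPFIA4, a liprin scaffold gene among the HIF targets, was at 108 ± 19.03 CPM in the CoCl2-tolerant and 0.847 ± 0.454 CPM in the low-glucose-tolerant line (log2 fold change 6.98 ± 0.25). TXNIP was at 299 ± 11.2 and 3.68 ± 0.347 CPM, and CLVS1, a lipid-binding protein of endosomes, at 13.8 ± 1.73 and 0.161 ± 0.129 CPM. The largest differences the other way were KLHDC7B, with 5 counts against 669 (ratio 127, 95% counting interval 54.1 to 392), HSPA6, at 0.339 ± 0.111 against 38.0 ± 10.2 CPM, and LAMP3, at 0.424 ± 0.102 against 37.2 ± 8.27 CPM. All 6 passed edgeR's test with adjusted p of 4.19e-09 or less. The log2 fold change of CLVS1 went from 6.38 to 7.23 without low-glucose-tolerant replicate 2, and that of KLHDC7B from -6.89 to -8.40 without CoCl2-tolerant replicate 2. PPFIA4 lies on chromosome 1, 203026498 to 203078740, TXNIP on chromosome 1, 145992435 to 145996600 and LAMP3 on chromosome 3, 183122213 to 183163839 (GRCh38). In total 11440 of 17902 genes differed (63.9%), 5707 higher and 5733 lower in the CoCl2-tolerant line. This balance depends on the scaling, since library totals gave 6261 higher and 5023 lower. Of the 11440 genes, 5632 differed at least 2-fold (3265 and 2367), against 2673 of 11673 with the stricter filter, and libraries did not overlap in 63.1% of genes, against 10% by chance.

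HIF targets were higher in the CoCl2-tolerant line for 39 of 44 genes and lower for 3 (camera adjusted p = 2.11e-23), and G2/M genes for 38 of 38 (camera adjusted p = 7.02e-42). ER chaperone genes were lower there for 31 of 36 and higher for 1 (adjusted over the list alone, 32 and 1; camera adjusted p = 1.48e-15), and epithelial genes lower for 17 of 21 and higher for 2 (camera adjusted p = 5.25e-06), with the tight junction gene CLDN3 at 2.67 ± 0.264 against 17.1 ± 2.99 CPM. These were the 4 lists of 13 called whose call held with an estimated correlation. With the preset correlation alone, glycolysis genes were higher for 18 of 24 and lower for 4 (camera adjusted p = 1.86e-09, and adjusted p = 0.155 with an estimated correlation), with ENO2 at 478 ± 77.2 against 58.4 ± 4.99 CPM. Glucose-sensing genes were higher for 4 of 10 and lower for 3 (camera adjusted p = 9.78e-04, and adjusted p = 0.0532 with an estimated correlation), a call also lost with the length and GC trend removed (adjusted p = 0.0976, the highest over the alternatives). DNA replication genes were higher for 36 of 44 and lower for 2 (37 and 3 adjusted over the list alone; camera adjusted p = 7.53e-11, and adjusted p = 0.106 with an estimated correlation). Sterol synthesis genes were higher for 14 of 25 and lower for 5 (14 and 7 adjusted over the list alone; camera adjusted p = 0.0354, and adjusted p = 0.277 with an estimated correlation). Mesenchymal genes were higher for 22 of 35 and lower for 9 (camera adjusted p = 1.51e-05, and adjusted p = 0.182 with an estimated correlation).

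Integrated stress response targets were lower in the CoCl2-tolerant line for 29 of 35 genes and higher for 4 (camera adjusted p = 1.71e-08, and adjusted p = 0.132 with an estimated correlation). STC2, a secreted stanniocalcin, was among the higher ones, at 839 ± 63.9 against 237 ± 15.1 CPM. Genes activated by p53 were lower for 15 of 25 and higher for 2 (camera adjusted p = 0.00281, and adjusted p = 0.0532 with an estimated correlation), metal response genes lower for 12 of 17 and higher for 2 (camera adjusted p = 0.0150, and adjusted p = 0.106 with an estimated correlation). Ribosomal protein genes were lower for 58 of 61 and higher for 1 (camera adjusted p = 3.43e-09, and adjusted p = 0.522 with an estimated correlation). HMOX1 differed by a log2 fold change of 0.39 ± 0.15 (edgeR adjusted p = 0.0302). That call was lost without CoCl2-tolerant replicate 1 (0.107), without low-glucose-tolerant replicate 1 (0.124, the highest over the alternatives) and with only the 2 groups in the fit (0.0548). MT2A differed by -0.52 ± 0.16 (edgeR adjusted p = 0.00997, and 0.0509 without low-glucose-tolerant replicate 3, the highest over the alternatives). ABCB1 differed by 0.26 ± 0.14 (edgeR adjusted p = 0.110, or 0.0385 without low-glucose-tolerant replicate 2, over a range of 0.0384 to 0.524).

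The senescence list did not pass in the direct comparison (camera adjusted p = 0.0535, 10 higher and 6 lower of 19). It passed without CoCl2-tolerant replicate 2 (0.0388), without low-glucose-tolerant replicate 3 (0.0348) and with library totals (0.0420), over a range of 1.02e-04 to 0.363. Fatty acid synthesis genes were higher for 9 of 13 (camera adjusted p = 0.0664, or 0.0141 without low-glucose-tolerant replicate 2 and 0.0133 with the length and GC trend removed, where 0.392 was the highest over the alternatives). For the lists left, counts higher and lower in the CoCl2-tolerant line follow with the camera adjusted p in brackets. They were 14 and 24 of 50 secretory factors (0.488), 3 and 6 of 17 Wnt and stem cell genes (0.185), 15 and 16 of 44 interferon-stimulated genes (0.708) and 9 and 13 of 31 BCL2 family genes (0.708). Respiratory subunits counted 7 and 12 of 53 (4 and 7 adjusted over the list alone; 0.665), mitochondrially encoded genes 2 and 4 of 13 (0.555), NF-kappaB targets 10 and 9 of 23 (0.791) and intestinal markers 1 and 4 of 6 (0.1998). Median and mean or test differed in sign for NRF2 targets (9 and 11 of 29, median 0.07, mean -0.06, 0.708), drug genes (8 and 10 of 28, 0.07, -0.20, 0.823) and inositol phosphate genes (14 and 16 of 42, 0.06, -0.06, 0.665). The same held for autophagy genes (7 and 9 of 38, median 0.09, mean -0.04, 0.708) and leukocyte markers (1 and 3 of 9, -0.36, 0.08, 0.873). Histone genes were higher for 6 of 14 (0.185). Fibroblast markers had a median of -1.74 but a test direction of higher (2 and 2 of 7, 0.333), and 1 of 4 endothelial markers was lower.

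Fold changes were also set out along the chromosomes for 10413 expressed autosomal genes, a summary chosen after the values were seen. In the low-glucose-tolerant line the median log2 fold change against control was 0.61 over 518 genes of chromosome 7 (95% bootstrap interval over genes 0.47 to 0.66) and 0.55 over 500 genes of chromosome 16 (0.47 to 0.63). It was -0.57 over 499 genes of chromosome 5 (-0.64 to -0.50) and -0.57 over 355 genes of chromosome 15 (-0.67 to -0.46). Intervals for 10 other autosomes also lay off 0 in this line, with medians of -0.32 for chromosome 13, -0.26 for 4, -0.17 for 10 and 14, -0.15 for 2, 0.12 for 12, 0.14 for 22, 0.15 for 20 and 0.19 for 9 and 19. With the length and GC trend removed, the medians were -0.02 for chromosome 13, 0.01 for 10, 0.02 for 22 and -0.04 for 19. For the others they were -0.11 for 4, -0.13 for 14, -0.07 for 2, 0.15 for 12, 0.17 for 20 and 0.19 for 9. In the CoCl2-tolerant line, compared with the same control libraries, the autosome medians lay between -0.10 and 0.08. The same 4 chromosomes moved in the same directions there, with 0.06 (0.02 to 0.11) for chromosome 7, 0.08 (0.04 to 0.12) for 16, -0.09 (-0.13 to -0.06) for 5 and -0.10 (-0.17 to -0.05) for 15. Intervals for chromosomes 4 (-0.09), 14 (-0.05), 19 (0.08) and 20 (0.06) also lay off 0 in that line. The chromosome 19 median was 0.20 in CoCl2-tolerant replicate 1, against 0.002 and 0.04 in replicates 2 and 3.

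**Figure D4:**
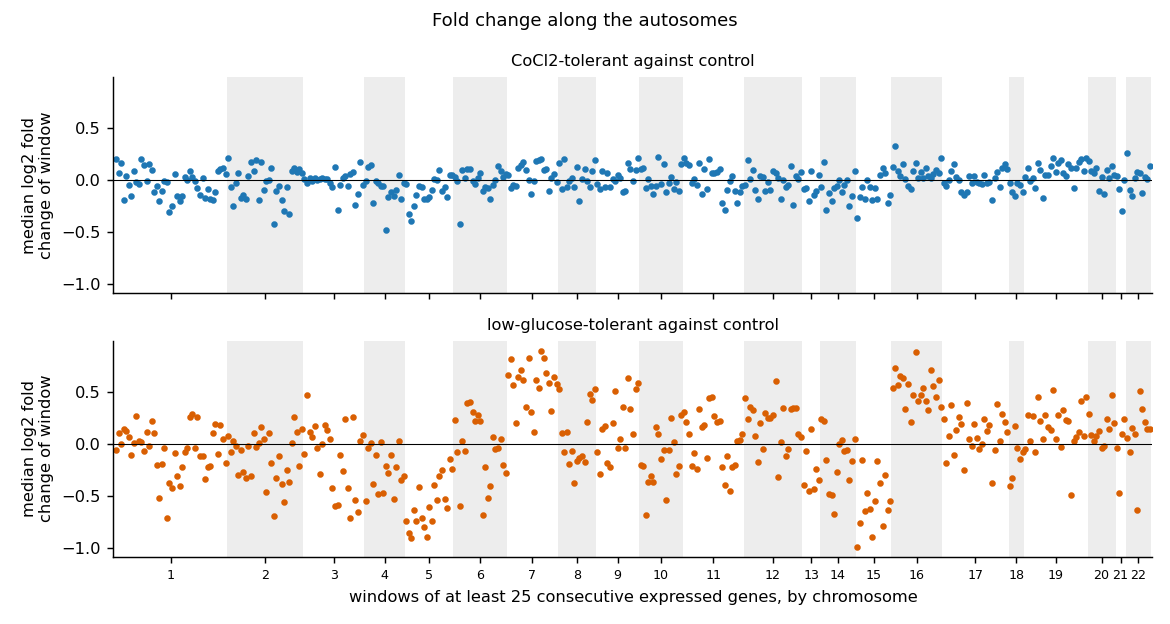
Median log2 fold change against control of windows of at least 25 consecutive expressed genes, in order along the 22 autosomes, in the CoCl2-tolerant (top) and low-glucose-tolerant (bottom) lines. In the bottom panel the windows of chromosomes 7 and 16 lie above 0 and those of chromosomes 5 and 15 below 0.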

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

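The length and GC trend test of the ribosomal protein genes was chosen after the result was seen. The values in the first paragraphs are direct contrasts of CoCl2-tolerant over low-glucose-tolerant cells, which test whether the lines differ in their change from the shared control. They were looked at more closely because that test passed. No group had 4 to 10 libraries, so no test for outlying libraries was made, but low-glucose-tolerant replicate 2 lay apart from its group on the second principal component (-19.9, against -0.73 and 1.59).

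Of 22 genes fixed by name 21 were tested, and 20 differed between the lines by edgeR's test. ER stress and stress response genes were lower in the CoCl2-tolerant line, by log2 fold changes of -3.16 for HSPA5, -2.83 for DDIT3, -2.37 for XBP1, -1.90 ± 0.12 for TRIB3, -0.71 for ATF4, -1.31 ± 0.17 for ASNS (with shared exon bases), -1.34 for GDF15 and -0.84 for CDKN1A. Growth and nuclear lamina genes were higher there, with 3.20 for MKI67 and 2.26 for LMNB1. Hypoxia and glucose genes were higher, with 6.34 for TXNIP, 1.31 for SLC2A1 and 0.81 for VEGFA. CA9 was 71.0-fold higher against a floor of 3 counts over the group, and the lower limit of its counting interval was 57.2-fold. HMOX1 was at 0.39 and MT2A at -0.52, the calls that ended without single libraries in the report. Among genes of inositol hexaphosphate metabolism the values were -0.69 for IPPK, -0.47 for ITPK1 and 0.44 for MINPP1.

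Of the 30 lists, 13 differed between the lines by limma's camera with the preset correlation. The median log2 fold changes were 2.15 for G2/M genes, 1.51 for HIF targets, -1.09 for ER chaperones and -1.36 for epithelial genes, the 4 calls that held with an estimated correlation. The other medians were -0.84 for integrated stress response targets, 1.35 for glycolysis, 0.18 for glucose sensing, 1.13 for DNA replication, 0.40 for sterol synthesis, -0.58 for p53 targets, -0.52 for metal response, 0.74 for mesenchymal and -0.99 for ribosomal protein genes.

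Ribosomal protein genes had a median of 1.44 against control in the low-glucose-tolerant line. They took 7.25% of the counts in replicate 2, against 9.38 and 10.8% in the others of that group. With the length and GC trend removed the median was 1.24, which argues against that trend as the whole cause. Other short abundant mRNAs might rise alike, for a technical reason such as RNA quality or size selection. The 170 genes matched on length, GC content and level had a median of 0.29 (95% bootstrap interval 0.16 to 0.44). The match on level was incomplete, with a median log2 CPM of 8.56 against 9.21 for the ribosomal protein genes. The interval of 0.16 to 0.44 crosses 0.36, the bound set from the list median under which the matched genes would count as not rising alike. The explanation by short abundant mRNAs therefore stays open for part of the rise. A change in ribosomal protein mRNA in the tolerant line is the biological explanation, and it was not tested apart from these.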

How the results depend on the processing

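Removing the length and GC trend, leaving out mitochondrially encoded genes and leaving out chromosomes 5, 7, 15 and 16 were tests chosen after the data were seen. Counts of changed genes in the CoCl2-tolerant, low-glucose-tolerant and direct comparisons (6459, 12394 and 11440) were 6383, 12163 and 11244 with DESeq2, 6443, 12387 and 11445 with its size factors, and 6325, 12301 and 11284 with library totals. With library totals 44.9% of the calls in the low-glucose-tolerant line were higher, against 49.98% with TMM, and 55.5% in the direct comparison, against 49.9%. They were 6822, 13663 and 12421 with no filter, 8552, 12027 and 10027 with only the 2 groups compared, and 7922, 13060 and 12287 with the trend removed. Without mitochondrially encoded genes they were 6429, 12361 and 11387, and without the 4 chromosomes 5347, 10014 and 9179 of 14673 genes. With each library left out in turn the counts ranged over 4463 to 7965, 11373 to 12903 and 10476 to 11836, and those of at least 2-fold over 1743 to 2135, 6398 to 7005 and 5533 to 5860. The stricter filter gave 779, 3404 and 2673 of 11673 genes of at least 2-fold, against 1983, 6572 and 5632. Log2 fold changes of the genes it kept moved by medians of only -0.01, -0.10 and 0.08. The 2-fold counts of the main fit therefore rest to a large part on the genes at low levels that this filter leaves out. Genes changed the same way in both lines (4079) ranged over 2754 to 5186 with each library left out and over 3091 (stricter filter) to 5089 (only the 2 groups compared) in the other alternatives.

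Lists called by camera (20, 14 and 13) were 9, 5 and 4 with an estimated correlation, and fry, which does not compare a list with other genes, called 24, 25 and 22. In the CoCl2-tolerant line fry did not call respiratory subunits (adjusted p = 0.221) or ribosomal protein genes (0.0630). The estimated correlation between members was 0.65 and 0.79 for these lists, against the preset 0.01. Both calls were also lost by camera with that estimate. Mitochondrially encoded genes, with an estimate of 0.69, were called by fry (adjusted p = 0.00307). The cause was not tested. They ranged over 20 to 20, 13 to 15 and 13 to 14 with each library left out, and were 18, 13 and 13 with the trend removed. Over named genes and alternatives, 6554 values kept their side of the threshold, 84 no longer passed and 10 newly passed. For lists the counts were 1185, 40 and 35. Direction was compared only for values that passed in the main fit or the alternative, and none of these reversed. A block for the replicate number gave 6091, 12118 and 11135 genes, 20, 14 and 13 lists, and 3870 genes in both lines. The pseudocount alternative was not run, since the files hold counts. Depth limits genes near 3 counts per library, 0.0918 to 0.119 CPM, and in the self-test 1.5-fold changes were recovered in 46.3 to 55.3% of cases.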

Other observations

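The tests of the length and GC trend on chromosomes, of loss of intestinal markers during growth and of a wrong cell line label were chosen after the result was seen, and so were the 4 chromosomes. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 6459 genes in the CoCl2-tolerant, 12394 in the low-glucose-tolerant and 11440 in the direct comparison, and the highest other split gave 0 by edgeR's adjusted test in each (311, 275 and 1383 at an unadjusted p under 0.05). For genes of at least 2-fold the real counts were 1983, 6572 and 5632, and the highest other again 0. For lists the real counts were 20, 14 and 13, and the highest other 16, 14 and 14. As many lists were called in 1, 2 and 3 of the 10 splits. For genes changed the same way in both lines, 1 of 100 drawn splits of the 9 libraries, the real one, gave 4079, and the highest other gave 607. The other splits mix groups that differ strongly, and both comparisons share the control libraries. The count therefore shows that the groups differ, and it cannot decide whether the lines share a response.

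Chromosome-wide shifts appeared in the low-glucose-tolerant line, with genes of chromosomes 7 and 16 higher and of 5 and 15 lower. Smaller medians of 10 other autosomes, -0.32 to 0.19, also had intervals off 0. With the length and GC trend removed, those of chromosomes 13, 10, 22 and 19 came to -0.02, 0.01, 0.02 and -0.04. The rest of the 10 kept their direction. The smallest of the medians of chromosomes 5, 7, 15 and 16 was 0.38 with that trend removed. This argues against the trend as the whole cause for those 4. At least 72.6% of each chromosome's genes lay on the side of the shift, where genes of the other autosomes moved by the same medians give 74.9 to 76.9%, and 69 of 73 windows of at least 25 genes (94.5%) lay on that side beyond the central range of windows elsewhere in the CoCl2-tolerant line, -0.22 to 0.18. These shares describe chromosomes picked for their medians and test no explanation, and 162 of 334 windows on the other autosomes (48.5%) also lay beyond that range in the low-glucose-tolerant line. A difference in DNA copy number may underlie the shifts, but no DNA was measured, and it cannot be told apart from regional regulation.

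Intestinal differentiation markers were near 0 in every group, with 26 of 29 listed genes under 1 CPM throughout, and CDX2 and KRT20 at 1 and 2 counts over all 9 libraries. Of the listed genes, 0 share most of their exon bases with another gene, which argues against reads lost to overlapping genes. In the control group 2 of the fixed genes reached 1 CPM, so the low level was already part of the untreated line, which is the observation itself and no separate test of loss during growth under stress. CA2 was at 2.31, 1.15 and 2.10 CPM and CHGB at 1.75, 3.17 and 10.5 CPM in control, CoCl2-tolerant and low-glucose-tolerant cells. Whether a wrong cell line label explains the 26 genes cannot be told apart from a line that lacks these markers, because no reference library of HCT-15 was used here.

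Some genes were chosen after their values were seen, and their levels in control, CoCl2-tolerant and low-glucose-tolerant cells follow as means ± SD in CPM. PAX8, a transcription factor of kidney, thyroid and Müllerian lineages, was at 568 ± 11.4, 577 ± 17.1 and 277 ± 25.7, and CDH16, a kidney cadherin, at 26.3 ± 0.393, 4.25 ± 0.185 and 8.61 ± 1.505. FOLR1, a folate receptor, was at 83.0 ± 3.77, 14.7 ± 1.82 and 3.68 ± 0.733, and the mesenchymal filament gene VIM at 1179.8 ± 65.1, 1969 ± 112 and 2621 ± 379. The epithelial genes KRT8 and EPCAM were at 658 ± 3.24, 494 ± 43.0 and 1297 ± 197, and at 54.7 ± 3.10, 21.8 ± 1.99 and 55.8 ± 14.4.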
